A study of Mus musculus with 6 samples.

How the data were processed

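Liver RNA of C57BL/6 mice was measured in 6 libraries. Of these, 3 came from wild-type animals (CON 1 to 3) and 3 from animals whose hepatocytes lack CD36, a cell-surface receptor and transporter of long-chain fatty acids (LKO 1 to 3). Per the labels, the diet of all animals supplied 60% of its energy as fat and was given for 16 weeks. RNA was isolated with TRIzol and treated with DNase I, and standard Illumina libraries were made. The labels give a group and a number for each library. They do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical.

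The deposited values are FPKM per gene and library, made by the authors and rounded to 2 decimals. FPKM are fragments divided by the length of the gene and by the mapped fragments of the library. Per the submitters' processing notes, HISAT2 (an aligner) and StringTie (an assembler that estimates transcript abundance) were used with the mouse genome build mm9. Versions, options, the annotation release and any strand setting are not given in the sources used here. The deposited file also gives a length in bases for each gene, per its header. A few very abundant transcripts in 1 library lower the FPKM of all its other genes. Genes with near-identical copies, such as the major urinary proteins (Mup), and mitochondrial genes with nuclear copies share reads, and their single values are uncertain.

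The deposited file held 56536 lines below its header. Of these, 2 lines continued an overlong annotation text and held no values, which left 56534 genes or loci. A total of 55536 were Ensembl genes, of which 55450 were found by identifier in the GENCODE M21 annotation, and 998 were assembled loci with no gene name. No coordinates are printed here, because the reference used for the GC content of transcripts is of a later build than the one in the submitters' notes. Whole reads could not be recovered, since FPKM times length did not fall on multiples of 1 step. No count model was therefore fitted, and the depth in reads is unknown. The sum of the FPKM of a library is a matter of scale and not its depth.

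The comparison was LKO against CON. Genes with a mean FPKM of at least 1 over the 6 libraries (11104, among them 332 assembled loci) were taken to log2(FPKM + 1). They were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. SE is the moderated standard error, and SD is over the 3 libraries of a group on the FPKM scale. Cd36 was also tested with an exact two-sided permutation test of its 6 FPKM values, for which 3 libraries against 3 allow no p below 0.1.

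A total of 46 lists of genes were fixed before the data were examined, and so were the design, the tests and the rule for naming genes. The lists cover metabolic pathways, stress and immune responses, sex-biased liver genes, and markers of liver and other cell types. Lists with at least 3 tested members (42) were tested together with limma's camera, which compares a list's members with the other genes. Camera was run with a preset correlation between genes of 0.01, and again with the correlation estimated for each list. limma's fry was run as an alternative. It asks whether a list's members move 1 way on balance and does not compare them with other genes. Within a list, p-values were also adjusted over the list alone, with no adjustment across the lists.

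The text names genes by this rule. Cd36 is given in every library. Insig1, Insig2, Srebf1, Fasn, Acaca, Scd1, Pparg and Ppara are given whatever their result. Of the genes past the threshold whose groups do not overlap and whose symbol is not a Gm or Rik number, up to 12 per direction with the largest fold change are given. Where fewer than 6 pass in a direction, those with the smallest unadjusted p fill up to 6 and are given as values that did not pass. Of each list described, up to 4 members with the smallest unadjusted p are given. Some genes that the rule names are not described here. Genes named outside this rule were chosen after their values were seen, and this is said where they appear.

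The steps were tested on simulated data for LKO against CON, with log2 values of 11104 genes drawn at the spread of these libraries. Over 5 draws, the limma test recovered 41.5%, 84.5% and 95.8% of the genes changed by a log2 fold change of 1, 2 and 3. It made 10.2 false calls per draw over all sizes. The changed genes, 335, 335 and 330 over the draws, were taken only from genes above a minimum level. No trend between libraries was simulated. These rates therefore do not give the power for the real libraries. Camera found a list of 20 genes shifted by -0.8 in 20 of 20 draws and called no unshifted list. The simulated genes were drawn independently of each other, so this gives no rate of false list calls for real libraries, in which the genes of a list are correlated. The alternatives were a pseudocount of 0.1, no filter or a filter at a mean FPKM of 5, median-ratio scaling, quantile normalization, removal of mitochondrial genes with rescaling, and eBayes without the trend. Further alternatives were limma's array weights, the library number as a block, each library left out in turn, a log2 fold change of at least 1, and the other list tests. Alternatives added after the data were seen removed from each library its trend with gene length, or with length and GC content, or estimated the array weights gene by gene. The trends were natural splines with 4 degrees of freedom, and 10766 genes had a GC value. Tables were handled with the R package data.table (version 1.17.8). Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 served for the exact test and the plots.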

Results

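Livers of mice on a high-fat diet were compared between animals with CD36 deleted in hepatocytes (LKO, n = 3 libraries) and wild-type animals (CON, n = 3). The comparison asks how the liver transcriptome differs when hepatocytes lack this fatty acid transporter. The libraries held 10614 to 11311 genes at an FPKM of at least 1. The FPKM of a library summed to 831928, 928647 and 976871 in CON 1, CON 2 and CON 3 and to 1179405, 1271880 and 959442 in LKO 1, LKO 2 and LKO 3. The depth in reads is unknown. The mitochondrially encoded genes took 3.88% to 6.18% of the summed FPKM in the CON libraries, and 5.27%, 10.1% and 4.14% in LKO 1, LKO 2 and LKO 3. The major urinary proteins, which male mouse liver secretes in large amounts, took 6.22%, 15.6% and 22.1% in CON 1, CON 2 and CON 3. Their share was 29.4%, 28.9% and 23.9% in LKO 1, LKO 2 and LKO 3.

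Cd36 (ENSMUSG00000002944), the deleted gene, was listed at 61.95, 26.49 and 19.66 FPKM in CON 1, CON 2 and CON 3. It was at 2.73, 3.70 and 10.22 FPKM in LKO 1, LKO 2 and LKO 3. Its mean was 36.0 ± 22.7 FPKM in CON (SD, n = 3) and 5.55 ± 4.07 FPKM in LKO (SD, n = 3), a 6.49-fold difference of the means. Every LKO library lay below every CON library, and LKO 3 was closest to the CON range. The log2 fold change of -2.50 (SE 0.51) did not pass the threshold over all genes (limma, adjusted p = 0.163). The exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Without LKO 3 the log2 fold change was -2.98 with an adjusted p of 0.0164, in a range of 0.00118 to 0.486 over all alternative settings. The fit without LKO 3 cannot tell the group from a length trend of the libraries, given below. Cells other than hepatocytes also express Cd36, and the share of the signal they gave is unknown.

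**Figure D1:**
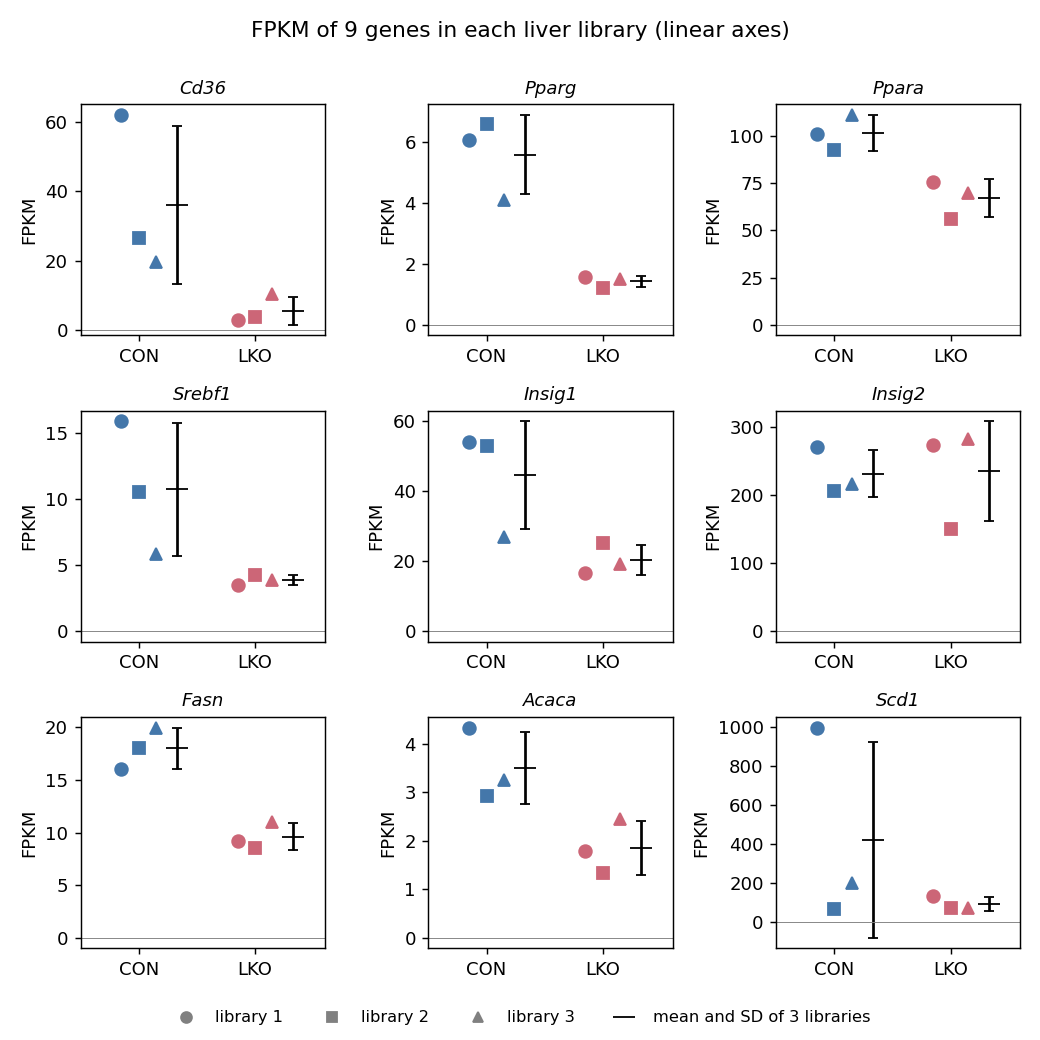
FPKM (linear vertical axes) of Cd36 and 8 genes of lipid metabolism fixed by name, in 3 CON (blue) and 3 LKO (red) libraries; the symbol shape gives the library number, and the bar beside each group is its mean with the SD of 3 libraries. Cd36, Pparg, Ppara, Srebf1, Insig1, Fasn and Acaca were lower in every LKO library than in every CON library, while the groups overlapped for Insig2 and Scd1.

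Pparg, the nuclear receptor that drives lipid storage genes, was at 5.58 ± 1.30 FPKM in CON and 1.43 ± 0.19 FPKM in LKO (SD, n = 3 each), a log2 fold change of -1.42 (SE 0.21). Srebf1, which encodes the main transcription factor of fatty acid synthesis, was at 10.8 ± 5.04 and 3.87 ± 0.39 FPKM, a log2 fold change of -1.18 (SE 0.32). Its target Fasn, the fatty acid synthase, was at 16.04, 18.09 and 19.95 FPKM in the CON libraries and at 9.19, 8.56 and 11.01 FPKM in the LKO libraries, a log2 fold change of -0.85 (SE 0.18). Insig1, which holds the SREBP proteins in the endoplasmic reticulum, was at 44.5 ± 15.4 and 20.3 ± 4.38 FPKM in CON and LKO. Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, was at 3.50 ± 0.74 and 1.85 ± 0.56 FPKM. Ppara, the receptor that induces fatty acid oxidation, was at 102 ± 9.41 and 67.2 ± 10.2 FPKM. None of these 6 passed over all genes, with adjusted p-values (limma) between 0.163 and 0.187. Their groups did not overlap, but that held for 2703 of 11104 genes in the lower direction. With length and GC trends removed, Ppara moved from -0.60 to -0.28 and Acaca from -0.66 to -0.30. Pparg, Srebf1, Insig1 and Fasn were then at -1.23, -0.90, -0.76 and -0.55. Trend removal also centres each library, as median-ratio scaling does. That scaling alone gave -0.33 for Ppara and -0.47 for Acaca. It gave -1.23, -0.94, -0.78 and -0.60 for Pparg, Srebf1, Insig1 and Fasn.

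Insig2, the second SREBP retention protein, was at 231 ± 34.4 FPKM in CON and 235 ± 73.3 FPKM in LKO. Its log2 fold change of -0.02 (SE 0.27, adjusted p = 0.968) turned to 0.25 after median-ratio scaling of the libraries. Scd1, the stearoyl-CoA desaturase, spread from 68.2 to 999 FPKM within CON and from 71.1 to 135 FPKM within LKO. Its difference was not larger than that spread (adjusted p = 0.322).

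Over all 11104 genes, 1 gene fell in LKO and 0 rose at an adjusted p under 0.05 (limma). The gene was Gm44002 (ENSMUSG00000108158), a predicted gene named here after its values were seen. It was at 5.23, 3.65 and 5.41 FPKM in the CON libraries and listed at 0, 0 and 0.14 FPKM in the LKO libraries (log2 fold change -2.45, adjusted p = 0.0226). At an unadjusted p under 0.05, 361 genes were higher and 2099 lower, where chance gives 555 in all. The median log2 fold change of all genes was -0.23. It was -0.01 after median-ratio scaling, with 1071 genes higher and 917 lower at the same unadjusted p. It was -0.46 with the mitochondrial genes removed and every library then rescaled to the same total. That rescaling itself shifts the values, since the summed FPKM differed between the libraries. The excess of lower genes therefore depends on the scale. List medians are given as fitted and are to be read against that median of -0.23, unless said to be minus that of all genes. The groups did not overlap for 435 genes in the higher and 2703 in the lower direction, 28.3% of genes where chance gives 10%. Without LKO 3, 2632 genes passed (521 higher and 2111 lower). In that fit the group coincided with a trend of the libraries with gene length. The Spearman rho of a library's deviations with length was -0.33 and -0.30 in LKO 1 and LKO 2. In CON 1, CON 2 and CON 3 it was 0.27, 0.10 and 0.29. No fit without LKO 3 had this trend removed, so its share of the 2632 calls is unknown. Without CON 1, CON 2, CON 3, LKO 1 and LKO 2 in turn, 3, 2, 5, 0 and 0 genes passed. Gm44002 was not among them without CON 1, LKO 1 or LKO 2 (adjusted p = 0.0581, 0.3 and 0.157). It also did not pass with a pseudocount of 0.1 (adjusted p = 0.125), with no filter (0.167), or with the length trend or the length and GC trends removed (0.111 and 0.0932). Nor did it pass with the library number as a block, where the smallest adjusted p of any gene was 0.0669.

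After Gm44002, the genes given for their smallest unadjusted p had no overlap between the groups, but none passed over all genes (adjusted p of 0.163 to 0.165, limma). In the lower direction they included Kalrn, a guanine nucleotide exchange factor (log2 fold change -1.48), Hlf, a transcription factor with circadian output (-1.46), and Pparg. They also included the carboxylesterase gene Ces1g (-2.50, with 78.8 ± 27.5 and 13.2 ± 5.28 FPKM in CON and LKO) and the immediate early gene Nr4a1 (-1.41). In the higher direction they included the potassium channel gene Kcnk1 (2.07, with 0.793 ± 0.708 and 6.69 ± 3.57 FPKM) and the stress-induced gene Gadd45b (1.37). The beta-actin gene Actb (0.87, with 238 ± 5.55 and 438 ± 53.7 FPKM), Btg3 (0.84) and the small nucleolar RNA host gene Snhg3 (0.82) were also among them. Without LKO 3, where group and length trend coincide, the adjusted p of these 10 genes ranged from 0.00674 to 0.0287.

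Genes of fatty acid synthesis were lower in LKO as a group. Of 20 tested members of the SREBP1 lipogenesis list, 20 had a negative log2 fold change and 18 lay below the median of all genes. After median-ratio scaling 18 were negative, and Lpin1 and Elovl5, named for this, were not. A total of 11 passed lower when adjusted over the list alone, against 0 over all genes. The list's median was -0.90 (camera, adjusted p = 1.1e-04 with the preset correlation, adjusted p = 0.759 with an estimated correlation). Mid1ip1, an activator of acetyl-CoA carboxylase, was at 10.7 ± 2.50 FPKM in CON and 3.55 ± 0.35 in LKO. The acetyl-CoA synthetase gene Acss2 was at 20.3 ± 5.66 and 8.58 ± 0.49 FPKM, and the lipogenic regulator Thrsp at 40.1 ± 11.8 and 15.9 ± 3.56 FPKM. Fasn was the other of the 4 members with the smallest p.

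Genes of cholesterol synthesis were also lower as a group. Of 23 tested members, 23 had a negative log2 fold change, 22 lay below the median of all genes, and 22 were negative after median-ratio scaling. A total of 5 passed lower when adjusted over the list alone, against 0 over all genes. The list median was -0.86 (preset adjusted p = 1.1e-04, adjusted p = 0.759 with an estimated correlation). Squalene synthase, Fdft1, was at 37.9 ± 11.1 and 14.0 ± 2.83 FPKM in CON and LKO. The sterol carrier gene Stard4 was at 9.91 ± 2.23 and 3.98 ± 1.35 FPKM, and the sterol desaturase gene Sc5d at 88.3 ± 16.5 and 41.3 ± 11.8 FPKM. Over the list alone, 0 members passed without CON 1 or without LKO 1, 8 without LKO 3 and 19 without CON 3. The count was 15 with the mitochondrial genes removed and the libraries rescaled, and 12 with array weights. The list median minus that of all genes, -0.64 in all libraries, was -0.26 without CON 2, -0.42 without LKO 3 and -0.99 without CON 3.

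The list of SREBP processing genes did not pass (preset adjusted p = 0.129), but did without CON 3 (adjusted p = 0.0468) and with no filter on low values (adjusted p = 0.00939). Over the list alone, 3 of 13 members passed lower. These were Srebf1, Insig1 and the SREBP escort gene Scap, the last at 30.0 ± 4.20 and 17.2 ± 4.93 FPKM in CON and LKO. Srebf2 had an adjusted p of 0.0775 over the list alone. Passes over a list alone, here and below, are to be read against 2099 of 11104 genes lower at an unadjusted p under 0.05. That number was 917 after median-ratio scaling, where Srebf1 and Insig1 had unadjusted p-values of 0.018 and 0.0461 (limma). Such passes were recounted under other settings only for the lipogenesis, cholesterol and clock lists.

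Among lists of glucose and fatty acid handling, none passed with the preset correlation, and single members passed over the list alone. The gluconeogenesis, bile acid and ChREBP lists were called lower in 4, 3 and 2 of 18 alternative settings. In the ChREBP and glycolysis list (median -0.48, preset adjusted p = 0.176) 3 of 16 members passed lower over the list alone. They included the pyruvate kinase gene Pklr (28.4 ± 11.1 and 9.90 ± 4.49 FPKM) and the glucose transporter gene Slc2a2 (71.3 ± 15.3 and 37.6 ± 10.3 FPKM). In the gluconeogenesis and glycogen list (median -0.60, preset adjusted p = 0.123) 4 of 15 passed lower over the list alone. They included the pyruvate carboxylase gene Pcx (log2 fold change -1.01), the glycogen phosphatase subunit gene Ppp1r3b (-1.31) and Fbp1 (-0.75). In the insulin signalling list (median -0.47, preset adjusted p = 0.278) 6 of 18 passed lower and 1 higher over the list alone. Among the smallest p were those of Pik3r1 (-1.72), the insulin receptor gene Insr (-0.71) and Gsk3b (-0.59). The genes of this list are long, with a median of 6585.5 bases. With length and GC trends removed the list median was -0.20, with Pik3r1 at -1.36, Insr at -0.34 and Gsk3b at -0.22. Trend removal also centres each library, and median-ratio scaling alone gave a list median of -0.26. Most of the move from -0.47 thus came with the centring. Under that scaling Pik3r1, Insr and Gsk3b were at -1.49, -0.46 and -0.38.

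The PPARA fatty acid oxidation list (median -0.33, preset adjusted p = 0.368) had 2 of 31 members past the threshold over the list alone. These were the acyl-CoA thioesterase genes Acot3 (-1.59) and Acot4 (-0.82). The list passed under quantile normalization (adjusted p = 0.0477) and with no filter on low values (adjusted p = 0.025). The fatty acid uptake and binding list (median -0.45, preset adjusted p = 0.677) had 1 member past it, and the list of lipid droplet and PPARG steatosis genes (median -0.27, preset adjusted p = 0.795) only Pparg. In the bile acid and sterol export list (median -0.50, preset adjusted p = 0.148) 5 of 19 passed lower over the list alone. The smallest p were those of the FGF co-receptor gene Klb (6.84 ± 2.52 and 2.27 ± 1.14 FPKM), the sterol exporter gene Abcg8 (-0.96), Slco1b2 (-0.98) and Nr1h4 (-0.62). In the lipoprotein assembly list (median -0.15, preset adjusted p = 0.325) 1 of 20 members passed lower over the list alone.

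Circadian clock genes were lower in LKO as a group, most so in LKO 1. Their median deviation from the CON mean was -1.37, -0.66 and -0.61 in LKO 1, LKO 2 and LKO 3. The list pools genes of opposite daily phase, so its median is not a measure of clock activity. In LKO 1 the activator gene Arntl was higher than in any other library, as given below. The labels used here give no time of collection, so a difference in it between libraries could not be tested. Of 18 tested members, 18 had a negative log2 fold change, 16 lay below the median of all genes, and 16 were negative after median-ratio scaling. A total of 6 passed lower when adjusted over the list alone, against 0 over all genes. The list median was -0.92 (preset adjusted p = 1.3e-04, adjusted p = 0.759 with an estimated correlation). Hlf was at 14.8 ± 1.57 FPKM in CON and 4.78 ± 1.15 in LKO. The repressor gene Cry2 was at 9.69 ± 1.51 and 3.78 ± 1.69 FPKM, and Cry1 at 2.61 ± 0.37 and 1.17 ± 0.29 FPKM. The list median minus that of all genes was -0.69, and -0.38 without LKO 1. Over the list alone, 13 members passed without LKO 3, 9 without LKO 2, 4 without CON 3 or LKO 1 and 3 without CON 2. The count was 3 under median-ratio scaling, quantile normalization, a filter at a mean FPKM of 5 or the removal of length or length and GC trends. It was 15 with the mitochondrial genes removed and the libraries rescaled, and 16 with array weights of either kind. The immediate early genes did not pass as a list (median -0.64, preset adjusted p = 0.0885), but were called lower in 8 of 18 alternative settings, among them median-ratio scaling (adjusted p = 0.0389). Of their 13 members, 13 had a negative log2 fold change, 10 after median-ratio scaling, and 3 passed lower over the list alone: Nr4a1, the phosphatase gene Dusp1 (-1.18) and Btg2 (-1.05).

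Relative to other genes, 8 lists were higher in LKO with the preset correlation, and for each of them the adjusted p was 0.759 with an estimated correlation. Of 34 genes of cytosolic ribosomal proteins, 33 lay above the median of all genes, with a list median of 0.27 (preset adjusted p = 2.1e-10), but 0 passed over the list alone. Rpl38 was at 441 ± 63.0 and 730 ± 216 FPKM and Rpl14 at 150 ± 18.1 and 217 ± 45.6 FPKM in CON and LKO. Of 12 mitochondrially encoded genes, 12 lay above the median of all genes (list median 0.69, preset adjusted p = 2.1e-06), and 0 passed over the list alone. Among them were mt-Co2 at 385 ± 96.3 and 623 ± 152 FPKM and mt-Cytb at 2546 ± 364 and 5237 ± 2838 FPKM, the latter with 8316 FPKM in LKO 2. This list did not pass under quantile normalization (adjusted p = 0.103). Without LKO 2 its median minus that of all genes was 0.48 against 0.92.

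Nuclear genes of oxidative phosphorylation had a median of 0.16 (preset adjusted p = 1.3e-04), with 31 of 36 above the median of all genes. The 4 members with the smallest p nevertheless had negative values, and none of them passed over the list alone. They were Sdha (-0.90), Sdhd (-0.59), Uqcrc2 (-0.55) and Atp5a1 (-0.51). As deviations from the CON mean, the median of the members was 0.34, 0.20 and -0.10 in LKO 1, LKO 2 and LKO 3. For the mitochondrially encoded genes it was 0.68, 1.63 and -0.08, and for ribosomal proteins 0.34, 0.42 and 0.11. With length and GC trends removed, the list median minus that of all genes moved from 0.39 to 0.23 for oxidative phosphorylation and from 0.50 to 0.31 for ribosomal proteins. The median gene lengths of these lists are 1591 and 1107 bases.

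Genes that are higher in male than in female liver had a median of 0.99 (20 of 22 above the median of all genes, preset adjusted p = 1.5e-09), with 0 past the threshold over the list alone. The fatty acid elongase gene Elovl3 was at 136 ± 11.4 and 266 ± 104 FPKM in CON and LKO. Mup1, whose reads cannot be told apart from those of other Mup genes, was at 2713, 8727 and 12245 FPKM in CON 1, CON 2 and CON 3 and 26708, 31551 and 12887 FPKM in LKO 1, LKO 2 and LKO 3. Mup21 (log2 fold change 1.22) and the selenium-binding protein gene Selenbp2 (2.42) overlapped between the groups. As deviations from the CON mean, the median of the members was -0.96, -0.04 and 0.90 in CON 1, CON 2 and CON 3. It was 1.49, 0.55 and 1.11 in LKO 1, LKO 2 and LKO 3, so the groups overlapped, with CON 3 above LKO 2. Without CON 1 the list median minus that of all genes was 0.71 against 1.21. The female-biased genes did not pass as a list (median -0.93, preset adjusted p = 0.172), with 4 of 9 lower over the list alone. These were Acot3, the steroid hydroxylase gene Cyp17a1 (-1.26), the prolactin receptor gene Prlr (-1.35) and Cyp2b9 (-4.00). Cyp2b9 was listed at 154.73, 12.47 and 2.09 FPKM in the CON libraries and at 0.07, 0.06 and 0.40 FPKM in the LKO libraries.

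**Figure D2:**
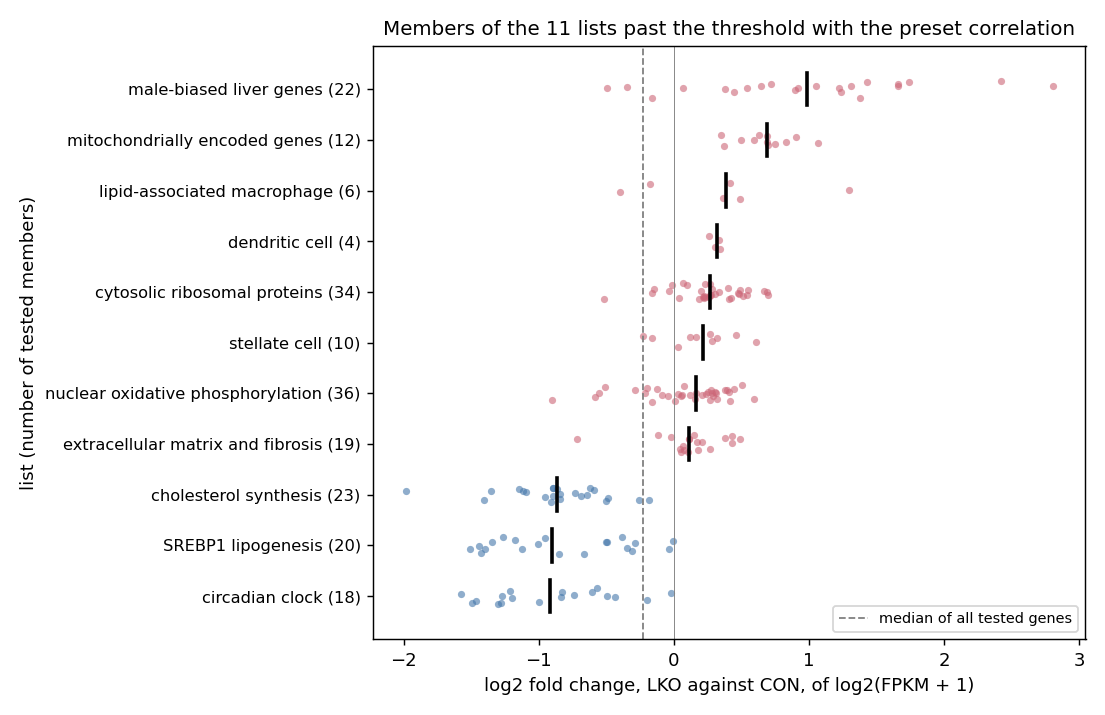
Log2 fold change (LKO against CON, horizontal axis, on the log2(FPKM + 1) scale) of each tested member of the 11 lists past the threshold with the preset correlation; each point is a gene, the black bar is the list's median, and the dashed line is the median of all tested genes. The list medians run from -0.92 for the circadian clock to 0.99 for male-biased liver genes, against -0.23 for all genes, and none of the 11 lists passed with an estimated correlation.

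Markers of 3 cell types other than the hepatocyte, and genes of the extracellular matrix, made up the other lists that were higher. Stellate cell genes had a median of 0.22 (10 of 10 above the median of all genes, preset adjusted p = 0.00479), and monocyte-derived or lipid-associated macrophage genes 0.39 (5 of 6, preset adjusted p = 0.0204). Dendritic cell genes had a median of 0.32 (4 of 4, preset adjusted p = 0.0336), and extracellular matrix and fibrosis genes 0.11 (18 of 19, preset adjusted p = 0.00324). In each of these lists 0 members passed over the list alone, and the adjusted p was 0.759 with an estimated correlation. Only 4 of the 9 dendritic cell genes were tested: H2-Eb1, H2-Ab1, H2-Aa and Cd74, all of MHC class II antigen presentation. Their estimated correlation was 0.97, so they act as little more than 1 measurement. This list therefore does not single out dendritic cells. Ecm1 was at 79.4 ± 5.15 and 127 ± 43.3 FPKM, Ly6c2 at 1.02 ± 0.10 and 1.69 ± 0.26, and H2-Eb1 at 25.9 ± 6.58 and 33.3 ± 9.52 in CON and LKO. Fibronectin, Fn1, the matrix gene with the smallest p, lay the other way at 284 ± 36.3 and 178 ± 61.4 FPKM. Without LKO 2 none of the 4 lists passed, with adjusted p-values of 0.0512, 0.103, 0.0504 and 0.113 in the order given. Without CON 2 the dendritic and matrix lists each had an adjusted p of 0.15, and without LKO 3 the macrophage and dendritic lists had 0.0635 and 0.324. With a filter at a mean FPKM of 5 none of the 4 passed either, with adjusted p-values of 0.0889, 0.107, 0.0571 and 0.0905. Over 18 alternative settings the stellate, macrophage, dendritic and matrix lists passed in 16, 11, 9 and 15, and the macrophage and dendritic lists did not pass with length and GC trends removed (adjusted p = 0.108 and 0.144). The matrix list's median minus that of all genes was 0.34 in all libraries, 0.14 without LKO 2, 0.23 without CON 2 and 0.55 without LKO 3. By median deviation from the CON mean the groups overlapped in all 4 lists. Stellate, macrophage and matrix genes were at -0.09, 0.03 and -0.16 in LKO 3, against -0.01, 0.25 and 0.20 in CON 1. Dendritic cell genes were at -0.11 in LKO 1 against 0.32 in CON 1. LKO 2 lay above every CON library for all but the dendritic list.

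Hepatocyte (median -0.60, preset adjusted p = 0.464), periportal (-0.44, 0.689) and pericentral (-0.27, 0.464) hepatocyte genes did not pass. Nor did Kupffer cell (-0.08, 0.537), sinusoidal endothelial (-0.21, 0.659), cholangiocyte (0.16, 0.259), B and plasma cell (0.40, 0.129), adipocyte (0.16, 0.187) and red blood cell (-0.13, 0.176) genes. The mean of the adipocyte genes was -0.07, opposite in sign to their median. Markers of neutrophils, T and NK cells, pancreatic acinar cells and skeletal muscle had 2, 2, 1 and 1 tested members and were not tested as lists. The elastase gene Cela1, the acinar marker tested, had a mean of 41.5 FPKM over the 6 libraries.

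The remaining lists did not pass with the preset correlation either. Their medians and preset adjusted p-values were -0.66 and 0.0982 for acute phase proteins, -0.40 and 0.0982 for autophagy and lysosome, and -0.33 and 0.81 for NRF2 antioxidant genes. They were -0.06 and 0.334 for CAR and PXR drug metabolism, -0.05 and 0.176 for the unfolded protein response, and -0.06 and 0.172 for the ATF4 stress response. For heat shock they were -0.48 and 0.866, for the interferon response -0.14 and 0.387, and for cytokines and chemokines -0.15 and 0.795. For the cell cycle they were -0.07 and 0.597, and for the genes of the Y chromosome and X inactivation -0.33 and 0.347. The acute phase list was nevertheless called lower in 9 of 18 alternative settings, among them median-ratio scaling (adjusted p = 0.0381). Its median deviation from the CON mean was -0.59, 0.71 and -0.17 in CON 1, CON 2 and CON 3. In LKO 1, LKO 2 and LKO 3 it was -0.62, -1.16 and -0.60, so CON 1 lay near the LKO level and CON 2 stood high. Il1b, at 4.77 ± 0.32 and 1.71 ± 0.60 FPKM, was the only member of these 11 lists past the threshold over its list alone. Camera placed 11 lists with a negative median above the other genes, whose median was itself negative. These were the ATF4, unfolded protein, CAR and PXR, interferon, cytokine, cell cycle, lipoprotein, lipid droplet, Kupffer cell, sinusoidal endothelial and red blood cell lists, none of which passed.

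**Figure D3:**
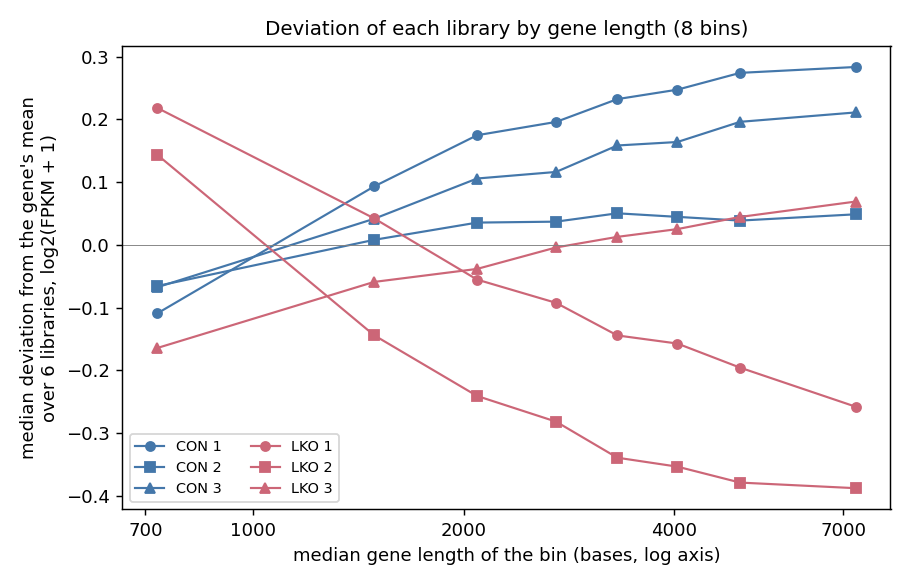
Median deviation of each library from the gene's mean over the 6 libraries (vertical axis, log2(FPKM + 1)) in 8 bins of genes by length (horizontal log axis, bases), for 3 CON (blue) and 3 LKO (red) libraries. LKO 1 and LKO 2 run from 0.22 and 0.14 in the shortest genes down to -0.26 and -0.39 in the longest, while LKO 3 runs from -0.16 up to 0.07, as the CON libraries also run upward.

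Gene length went with the fold changes. Over 11104 genes, which are not independent replicates, the log2 fold change and length had a Spearman rho of -0.30. The median log2 fold change was 0.14 in the shortest of 8 bins of genes and -0.37 in the longest. Within libraries, the deviation from the gene's mean had a rho with length of 0.27, 0.10 and 0.29 in CON 1, CON 2 and CON 3 and of -0.33, -0.30 and 0.21 in LKO 1, LKO 2 and LKO 3. With the trends of length and GC content removed, 0 genes passed (limma), with 897 higher and 1003 lower at an unadjusted p under 0.05. A total of 12 lists then passed with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.586). The lipogenesis, cholesterol and clock lists then had medians of -0.60, -0.55 and -0.60. Since trend removal also centres each library, these are to be read against median-ratio scaling alone, which gave -0.64, -0.63 and -0.70.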

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

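The removal of length and GC trends and the array weights estimated gene by gene were chosen after the data were seen, and the other settings before. The number of genes past the threshold, 1 as described, was 0 with a pseudocount of 0.1, with no filter, with a filter at a mean FPKM of 5, and with the length trend or the length and GC trends removed. The number was also 0 with the library number as a block. It was 2 with mitochondrial genes removed and the libraries rescaled, 5864 with array weights and 3072 with array weights gene by gene. It was 1 under median-ratio scaling, quantile normalization, eBayes without the trend and a log2 fold change of at least 1. Leaving out each library in turn gave 0 to 2632 genes, the highest without LKO 3, where group and length trend coincide. The array weights gave LKO 1 a weight of 13.8 and LKO 3 a weight of 0.196, so that fit rests largely on LKO 1. Gm44002 did not pass with a pseudocount of 0.1, with no filter, with either trend removal, with the library number as a block, or without CON 1, LKO 1 or LKO 2. The cause of the other shifts was not tested.

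Cd36 stayed negative in every setting run, from -2.98 to -2.03 without each library in turn. It passed the threshold with array weights (-2.86), with array weights gene by gene (-2.70) and without LKO 3. The number of lists past the threshold, 11 with the preset correlation, was 23 with no filter, 7 with a filter at a mean FPKM of 5 and 17 under quantile normalization. It was 0 with an estimated correlation and 0 with fry (smallest adjusted p = 0.0994, with 9 lists at an unadjusted p under 0.05). It ranged from 8 to 16 without each library in turn and from 9 to 13 in the remaining settings. The lipogenesis, cholesterol synthesis, circadian clock, ribosomal protein, male-biased and nuclear oxidative phosphorylation lists passed with the preset correlation in all 18 refits. The dendritic cell list passed in 9 of them, as did the acute phase list, and the immediate early genes in 8. Of the other lists not called, the gluconeogenesis and autophagy lists passed in 4, the bile acid list in 3 and no other list in more than 2. No list passed with an estimated correlation in any of them.

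Insig2 changed sign, past the threshold in no setting, and of the other genes fixed by name or given for their smallest p over all genes none did. Its log2 fold change was 0.249 under median-ratio scaling, 0.0929 under quantile normalization, 0.286 with array weights and 0.179 with array weights gene by gene. It was 0.235 with the length trend removed and 0.269 with the length and GC trends removed. Over the fits without each library in turn it ranged from -0.178 without LKO 3 to 0.272 without LKO 2, and was 0.0975 without CON 1. With the mitochondrial genes removed and the libraries rescaled it was -0.305. Of the 20 named genes other than Cd36, 14 came to pass without LKO 3, where group and length trend coincide, and 17 under each kind of array weights.

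The numbers 1 to 3 occur in both groups but are not said to mark a common origin. Deviations from the group means correlated over genes at -0.05, 0.17 and 0.07 between libraries of the same number. CON 2 and CON 3 correlated best with the LKO library of their own number and CON 1 with LKO 3 (0.06). Since this did not hold for every library, the numbers were not taken to pair them. With the replicate block 0 genes passed, so Gm44002 did not (smallest adjusted p = 0.0669), Cd36 had an adjusted p of 0.19, and 12 lists passed. Over the list alone, 18 cholesterol and 12 clock genes then passed. Depth in reads is unknown, and 2 decimals limit the values of low genes.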

Other observations

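The tests of the lists with length and GC trends removed were chosen after their results were seen, as was the division of the test of single libraries by list, and the other tests before. Single libraries stood apart in groups of genes, and the genes given here were chosen after their values were seen. CON 1 had Serpina1e, a male-biased gene, at 513.64 FPKM against 7002.38 and 6969.41 in CON 2 and CON 3 and 7658 to 12570 in the LKO libraries. It also held the highest values of Cyp2b9 (154.73 FPKM) and Scd1 (998.53 FPKM). A female animal as CON 1 is argued against by the Y-linked genes Ddx3y and Eif2s3y, at 11.29 and 17.74 FPKM in CON 1. In the other libraries they were at 7.53 to 10.86 and 13.83 to 17.53 FPKM. CON 2 had the highest median of the acute phase list, 0.71 above the CON mean. The lipocalin gene Lcn2 was at 285.88 FPKM in CON 2 against 11.27 and 46.84 in CON 1 and CON 3 and 8.72 to 11.6 in LKO.

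LKO 1 differed from the 5 other libraries in clock genes whose daily rhythms run in opposite phase. Arntl, the activator, was at 4.36 FPKM in LKO 1 against 0.80 to 2.24 in the others, and the output gene Dbp at 4.98 FPKM against 28.5 to 93.6. Per3 was at 0.33 FPKM in LKO 1 against 1.13 to 3.39, and Ciart at 0.49 against 1.85 to 7.18. The median of the clock list as a deviation from the CON mean was -1.37, -0.66 and -0.61 in LKO 1, LKO 2 and LKO 3. Hlf was below the CON range in LKO 2 and LKO 3 as well, at 4.16 and 6.10 FPKM.

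The split of the libraries by group was compared with the 9 other ways of dividing 6 libraries into 3 and 3, which are too few for a share under 0.05. The real split called 1 gene and the highest of the others 3, and 4 of the 10 splits called at least as many as the real one. For lists with the preset correlation the real split called 11 and the highest of the others 17, and 5 of the 10 called at least as many. At an unadjusted p under 0.05 the real split had 2460 genes and the highest of the others 1700.

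LKO 3 lay nearer to the CON libraries than LKO 1 and LKO 2 did, with a mean correlation over genes of 0.966 with CON and 0.941 with the other LKO libraries. A control library carrying the label of LKO 3 would sit no further than a left-out CON library along an axis from 2 CON libraries (0) to LKO 1 and LKO 2 (1), taken over 1000 genes. LKO 3 sat at 0.16, 0.25 and 0.33 and the left-out CON library at -0.13, 0.20 and 0.15 for the 3 axes, and the lowest of the former minus the highest of the latter was -0.0389, so a wrong label stays open, although the Cd36 of LKO 3 (10.22 FPKM) lay below that of every CON library. With length and GC trends removed, the mean correlation of LKO 3 with CON was 0.0148 above that with LKO 1 and LKO 2, but the single correlations overlapped (0.957 with CON 1, 0.960 with LKO 1), so these trends stay open too. A less complete deletion in LKO 3 was not tested.

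The lipogenesis and cholesterol synthesis lists were lower in LKO. Length and GC trends as the whole cause are argued against for lipogenesis. With both removed its median deviation from the CON mean was -0.53, -0.60 and -0.46 in LKO 1, LKO 2 and LKO 3, and -0.13 to 0.16 in CON. Chance alone keeps 3 and 3 libraries apart in 10% of cases, so this weighs only against the trends. For cholesterol synthesis the groups overlapped (-0.24 in LKO 2, -0.47 in CON 3), so these trends stay open there. The 95% bootstrap intervals of the list medians (2000 resamples) ran from -0.99 to -0.249 and from -0.68 to -0.47. They resample correlated genes and not libraries, so they do not decide this. No single library decided the lipogenesis list, whose median minus that of all genes was at most -0.556 when each was left out. For cholesterol synthesis the value reached -0.256 without CON 2, between the bounds set beforehand, so a single deciding library stays open. The deletion of CD36 remains an untested candidate explanation beside other differences between these 6 libraries, and neither list passed with an estimated correlation (adjusted p = 0.759).

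Ribosomal protein and nuclear oxidative phosphorylation genes, which have median lengths of 1107 and 1591 bases, were higher in LKO relative to other genes, though neither list passed with an estimated correlation (adjusted p = 0.759). Length and GC trends stay open as the whole cause for either list. With these trends removed, the median deviation of ribosomal proteins from the CON mean was 0.30, 0.45 and 0.20 in LKO 1, LKO 2 and LKO 3. In CON it was -0.18 to 0.14, so LKO 3 lay apart by less than the spread within CON. For oxidative phosphorylation the groups overlapped (-0.004 in LKO 3, 0.07 in CON 1). The lower ends of the bootstrap intervals were 0.216 and 0.0923, but these resample correlated genes and not libraries. Part of the shift went with the trends, as the medians minus that of all genes moved from 0.50 and 0.39 to 0.31 and 0.23. No single library decided either list, as leaving out each gave medians minus that of all genes of at least 0.357 and 0.292. This cannot detect a rise carried by 2 libraries. For oxidative phosphorylation the median deviation from the CON mean was 0.34 and 0.20 in LKO 1 and LKO 2 but -0.10 in LKO 3. The deletion of CD36 stays open as untested, and so do reads shared with pseudogenes. A difference in RNA integrity or library preparation may also contribute, since LKO 1 and LKO 2 had the opposite length trend to the other 4 libraries, and the labels give no batch to test it.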
